A study of Mus musculus with 3 samples.

How the data were processed

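Total RNA of RM1-MXRA7 and RM1-VE cells was measured on 3 Agilent mouse 2-colour arrays of 44397 spots, of which 1377 were controls and 43020 held 39429 distinct probes of 60 bases, 399 of them spotted 10 times. Per the labels, Cy3 held RM1-MXRA7 and Cy5 RM1-VE on all 3 arrays, with no dye swap, so a dye effect on a probe and a difference between the lines have the same sign everywhere. All 3 arrays lay on 1 slide with 1 scan date.

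Per the file headers, the authors deposited the scanner output of Agilent Feature Extraction, which the submitters' processing notes give as version 10.7.1.1. It holds each spot's mean and background intensity in both channels, the processed intensity that the software detrended and dye-normalized, and a log10 ratio of Cy5 over Cy3, which was not used for the values here. The deposited series matrix holds a linear ratio per probe. It equalled green over red processed signal within 1% for 100% of the values compared, so its scale and direction are known and it was not centred, and its column medians were 1.02, 1.03 and 0.972.

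Intensities were corrected with normexp (offset 50) and normalized by loess within each array with control spots at weight 0 and no scaling between arrays, in limma 3.58.1 under R 4.3.3. Ratios were turned to RM1-MXRA7 over RM1-VE. Control spots and spots with an outlier flag were left out, and spots of 1 probe were averaged. A probe was kept where it was well above background on all 3 arrays in at least 1 channel, which left 21791 probes. Array names were brought to RefSeq symbols (GRCm38.p6, names only) through the accession for 27508 probes, and 11921 kept the name in the file. Probe coordinates are those of the array files on mm9. A gene was represented by its kept probe of highest mean intensity, which gave 16819 genes, 4013 of them with more than 1 kept probe.

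Log2 ratios were tested against 0 with lmFit and eBayes of limma and adjusted by Benjamini-Hochberg, with thresholds of adjusted p 0.05 and, for large changes, an absolute log2 ratio of 1. Gene lists, 43 fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 5 members were kept, which left 42 lists. The erythroid and haemoglobin list had 1 kept member and was not tested. Named genes are Mxra7, the 12 largest rises and the 12 largest falls among genes past the threshold, in the same direction on all 3 arrays and well above background in both channels on all 3, the 4 largest bounds per direction among genes not well above background in 1 channel on every array, and up to 4 members per list with the smallest adjusted p. Names such as predicted genes, clones and accessions were passed over, 3 above the last named rise and 0 above the last named fall. Bounds used values per channel after loess and Aquantile, with the dim channel set at the lowest signal well above background or at its own value where higher.

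The log ratios were seen to run along the rows of the arrays. A surface over row and column, of polynomials of degree 4 alone and times log2 intensity, was therefore removed per array as an alternative added after the data were seen. The surface took 34.2%, 33.5% and 25.4% of the variance of arrays 1, 2 and 3, and the median SD between arrays went from 0.118 to 0.0951. Across genes, the ratios without the surface had a Spearman correlation of 0.93 with those from Agilent's processed signals, against 0.717 with the surface left in.

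The steps were tested on simulated data. With changes of 0.5, 1 and 2 on the log2 scale in 67, 67 and 66 of 16819 simulated genes, limma recovered 100% at each size, with 9 false calls. With a simulated surface added, 8903 unchanged genes were called before its removal and 25 after it, and 200 of 200 changed genes were recovered after it. Camera called the 1 shifted list and 0 others of 42. The simulated surface was a polynomial of the kind that is fitted, so its removal had to succeed and does not test a surface of another form. Simulated genes had the same spread and were independent, whereas the interferon response list had an estimated correlation of 0.49 in the data. The simulations therefore do not show the error rates in the data.

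Alternatives fixed before the data were examined covered the background correction, the normalization, the filter, the collapse of probes, the series matrix values, the test and the arrays left out in turn. Each array is a numbered pair of the 2 lines, so the ratio holds the pairing, and fits of the single channels with and without the array as a block were alternatives.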

Results

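RM1 is a mouse prostate cancer cell line. Per the labels, RM1-MXRA7 cells were transfected with MXRA7, named for matrix remodelling, and RM1-VE cells with the vehicle vector. Total RNA of both lines, taken in exponential growth on day 2, was compared on 3 Agilent 2-colour arrays, numbered as replicates 1 to 3. On every array RM1-MXRA7 was in Cy3 and RM1-VE in Cy5, so each array gave 1 log2 ratio per probe of RM1-MXRA7 over RM1-VE (n = 3). The number of arrays, 3, limits the precision. Of 39429 distinct probes, 21992, 23176 and 22284 were well above background in Cy3 on arrays 1, 2 and 3, and 22793, 24181 and 21787 in Cy5. Across 16819 genes the log2 ratios of the array pairs correlated with Pearson's r of 0.851, 0.785 and 0.813, where genes are not independent replicates. The labels do not say whether the replicates were separate transfections or cultures. The p-values measure only spread between these arrays, mostly as pooled over genes (13.6 prior against 2 residual degrees of freedom before surface removal). They do not rest on the SD of the single gene printed beside them alone.

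The first question was whether the transfected gene was higher in the transfected line. Mxra7 had a log2 ratio of 0.31 ± 0.14 (SD, n = 3; limma adjusted p = 0.00531), a 1.24-fold higher level, with values of 0.39, 0.39 and 0.15 on the 3 arrays. Its probe covers chromosome 11, 116673251 to 116673310 (mm9 coordinates from the array files), and has the sequence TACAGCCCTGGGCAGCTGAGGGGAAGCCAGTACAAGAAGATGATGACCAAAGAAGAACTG. A dimmer probe of Mxra7, at 116665685 to 116665744, gave 0.10 ± 0.04 (SD, n = 3). The call on Mxra7 ended when the trend of log ratios over the array surface was removed, with a ratio of -0.012 ± 0.05 (SD, n = 3; limma adjusted p = 0.893), and Agilent's processed signals gave -0.034. The dimmer probe lay at 0.067 ± 0.06 (SD, n = 3) with the surface removed and at 0.18 ± 0.12 in Agilent's processed signals, where it was positive on 3 of 3 arrays. Every direction below therefore rests on the dyes stated in the labels and was not checked by the transfected gene.

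A set of genes had large ratios in the same direction on all 3 arrays. Dye bias of single probes cannot be told apart from a difference between RM1-MXRA7 and RM1-VE cells, since no dyes were swapped. The largest falls among genes well above background in both channels were those of Magohb, which encodes a subunit of the exon junction complex, with a log2 ratio of -4.48 ± 0.22 (SD, n = 3), or 22.3-fold lower, and of Crip1, a gene for a cysteine-rich LIM protein, with -4.09 ± 0.28. In Agilent's processed signals Magohb lay at -5.84 and Crip1 at -4.18, so the fold of Magohb depends on the processing. The largest rises among those with an established symbol were of Tecpr2, a gene linked to autophagy, by 4.75-fold, Adck1 by 4.51-fold and Sel1l, an adaptor of protein degradation at the endoplasmic reticulum, by 4.03-fold. Some predicted genes, passed over by the naming rule, rose more. At an adjusted p of 0.05, limma called 7963 of 16819 genes, 4012 higher and 3951 lower in RM1-MXRA7, and 189 of them differed at least 2-fold, 65 upward and 124 downward. Most calls were small, since 6592 (82.8%) had an absolute log2 ratio under 0.5. The log ratios also ran along the rows of all 3 arrays, and with that surface removed 5243 genes were called, 2667 higher and 2576 lower. Both fits called 3469 genes in the same direction, 1675 up and 1794 down, and 153 genes differed at least 2-fold in both, 52 up and 101 down. A gene is described below as having risen, fallen or changed only where both fits called it in that direction, a rule chosen after the data were seen. Values are those before surface removal unless stated. Of 126 genes chosen by the naming rule and called in both fits, 38, all chosen from lists, had a ratio over 1.5 times smaller with the surface removed, and that ratio is given where a value of such a gene is printed below.

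**Figure D1:**
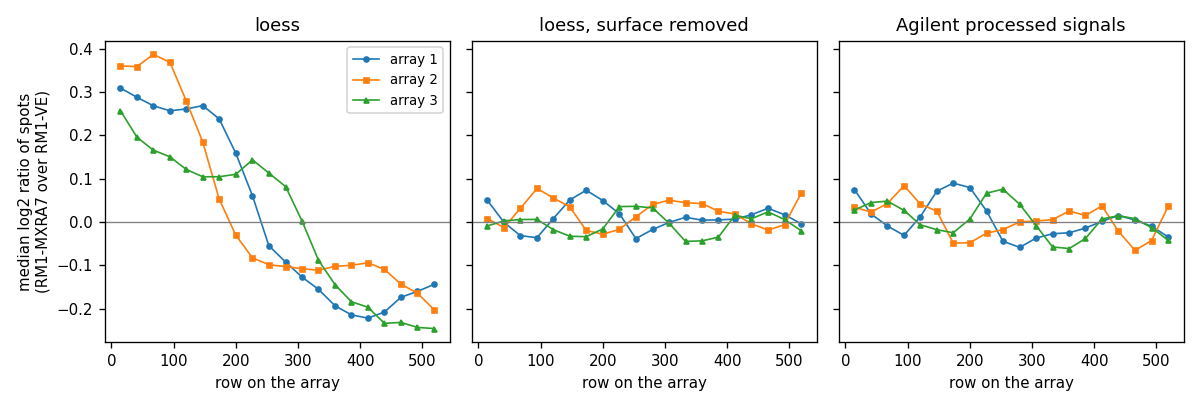
Median log2 ratio of RM1-MXRA7 over RM1-VE (vertical axis) of spots of kept probes in 20 bins of array rows (horizontal axis), with 1 line per array, after loess, after loess with the surface removed, and in Agilent's processed signals. After loess the first bin lies at 0.31, 0.36 and 0.26 on arrays 1, 2 and 3 and the last bin at -0.14, -0.20 and -0.25.

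The 12 largest falls were in genes of several kinds. Magohb (chromosome 6, 131234716 to 131235689) had a limma adjusted p of 4.16e-15 and Crip1 (chromosome 12, 114392029 to 114392088) of 3.68e-14. Pdlim4, a gene with PDZ and LIM domains, had a log2 ratio of -2.99, and Cdkn1c, an imprinted gene for an inhibitor of cyclin-dependent kinases, of -2.80. The interferon-induced oligoadenylate synthetase genes Oas1a and Oas1f had ratios of -2.63 and -2.39. Repin1 lay at -2.29 and Lmo1, which encodes a LIM-only transcription cofactor, at -2.28. The cyclic nucleotide phosphodiesterase genes Pde8a and Pde3b lay at -2.25 and -2.25, the oxoprolinase gene Oplah at -2.25 and Plac9a at -2.19. Each of the 12 was lower on 3 of 3 arrays, with SDs of at most 0.35. Agilent's processed signals gave larger falls for Pde8a, Cdkn1c and Plac9a, at -3.76, -3.71 and -3.05.

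Among the 12 largest rises of genes with established symbols and signal in both channels, 4 lay on chromosome 12. In that range 3 predicted genes were passed over, Gm2022, Gm2016 and LOC101056486, at 3.03, 2.04 and 2.04, named here after their values were seen. Tecpr2 (112209537 to 112209596) had a log2 ratio of 2.25 ± 0.36 (SD, n = 3; limma adjusted p = 2.14e-10), Adck1 (89699931 to 89699990) of 2.17 ± 0.18, Sel1l of 2.01 ± 0.23 and Tnfaip2 of 1.73 ± 0.28. On other chromosomes, the endothelin receptor type A gene Ednra rose by 1.96, the centrosomal gene Cntln by 1.93 and the fibrillar collagen gene Col3a1 by 1.83. Gng11, which encodes a G protein gamma subunit, rose by 1.76 and Renbp by 1.75. The fatty acid binding protein gene Fabp5 rose by 1.71 and the zinc finger gene Zfp764 by 1.67. Each of the 12 was higher on 3 of 3 arrays, and 1 of them is not named here. Agilent's processed signals gave 2.88 for Tecpr2 and 2.56 for Ednra. A dimmer kept probe of Adck1 lay at -0.31, opposite to the probe used, and 1 of Cntln at 1.15.

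**Figure D2:**
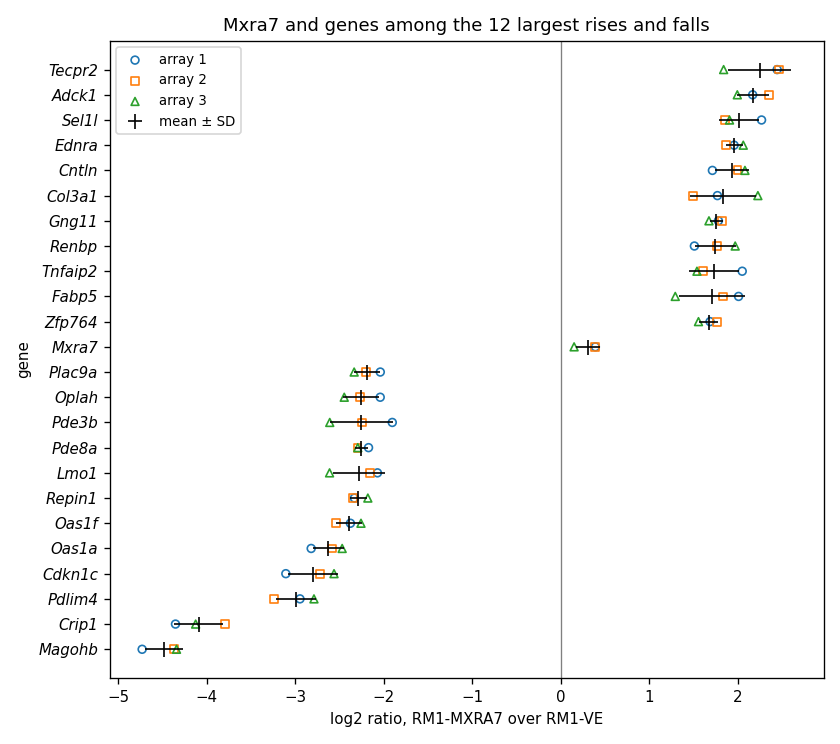
Log2 ratio of RM1-MXRA7 over RM1-VE (horizontal axis) on each of the 3 arrays, with the mean and SD, for Mxra7, the 12 largest falls and the 12 largest rises of genes with established symbols but 1 (vertical axis). Mxra7 has a mean of 0.31, the rises lie between 1.67 and 2.25, and the 12 falls between -4.48 and -2.19.

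The distal part of chromosome 12, from position 70000000, was singled out after its values were seen. Of 375 genes tested there, 18 rose and 4 fell at least 2-fold in both fits. The 18 are part of the 50 such rises among the 16601 genes with a position. Tecpr2, Adck1, Sel1l and Tnfaip2 are among the 18, and 8 others carry predicted-gene, accession or probe names. Those with a probe name start at 89218929 and 89219400, so the 18 may not all be separate genes. The 3 largest upward ratios of all genes also lie in this part, named after their values were seen. Gm2022 rose by 8.17-fold, while Gm21319 and Gm8300, without signal well above background in RM1-VE, were at least 41.1-fold and at least 12.2-fold higher. Of the 18, 8 start between 88858902 and 89699931, among them these 3 and Adck1. The other 13 genes tested in that stretch had a median of 0.10 with the surface removed and lay between -0.13 and 0.45. Crip1 is among the 4 of the segment that fell. The median of the 375 genes lay at -0.035 relative to other genes with the surface removed.

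**Figure D3:**
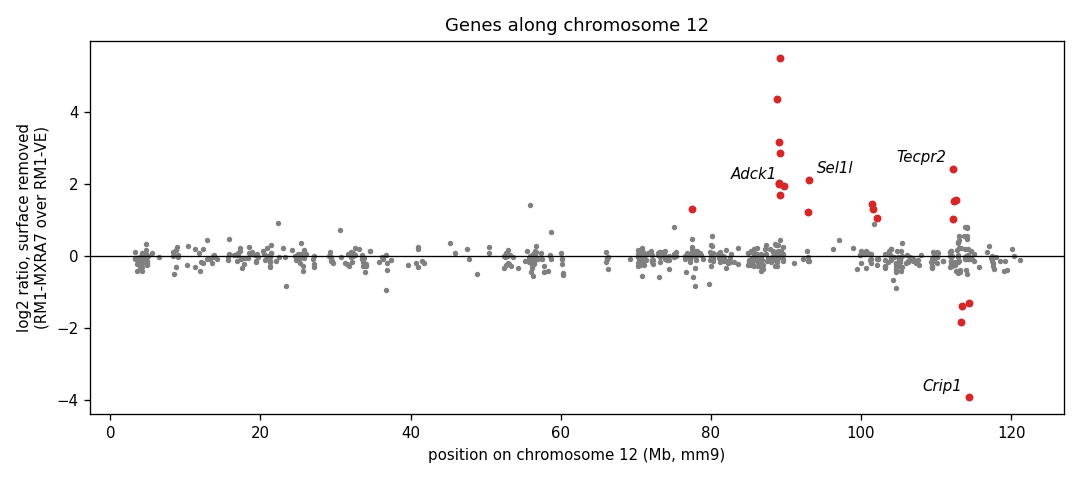
Log2 ratio of RM1-MXRA7 over RM1-VE with the surface removed (vertical axis) of 612 genes by position on chromosome 12 in Mb (horizontal axis, mm9), with genes from position 70000000 that differed at least 2-fold in both fits in red. The highest red points are those of Gm21319 and Gm8300, which had no signal well above background in RM1-VE, and Tecpr2 lies at 2.42 and Crip1 at -3.92.

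Other genes had signal well above background in only 1 of the lines, and their difference is given as a bound, open to dye bias. Ggh, the gamma-glutamyl hydrolase gene, was at least 15.8-fold lower in RM1-MXRA7 (limma adjusted p = 1.37e-14). Tmem185b was at least 6.77-fold lower. Cth, the cystathionine gamma-lyase gene, was 8.86-fold lower and Fahd2a 6.76-fold lower. For these last genes the bound equals the measured fold, since the dim channel's own value was used, so it is not a minimum. A dimmer kept probe of Cth lay at -2.63. In the other direction, Trim68 was at least 2.51-fold higher, Xlr at least 2.29-fold, Tmtc2 at least 1.82-fold and Zmat1 at least 1.59-fold higher. Among the rises, 5 genes with predicted-gene or probe names and bounds above the last of these were passed over, Gm21319 and Gm8300 with the largest. Among the falls, 0 were. The bounds were computed before surface removal, after which the log2 ratios of Trim68, Cth and Fahd2a, 1.27, -3.01 and -2.64, were slightly smaller than their bounds. The 32 genes chosen by size or bound kept their direction and their call in all 600 values computed for them under the alternatives. These reuse the arrays from which the genes were chosen, and none removes dye bias. Genes with a bound had no value with the filter on both channels.

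More interferon response genes fell than rose in RM1-MXRA7. Of 37 measured members, 18 fell and 3 rose in both fits. Of the oligoadenylate synthetase family, Oas1a fell by 2.63 on the log2 scale, Oas2 had a ratio of -1.39, Oasl2 of -1.13 and Oasl1 of -0.95. The 3 that rose were Usp18 at 0.86, Ifit2 at 0.52 and Ifitm1 at 0.53, named after their values were seen, with Ifit2 at 0.35 with the surface removed. Before surface removal 19 were lower, 7 higher and 11 did not pass, and 20 and 7 passed when adjusted over the list alone. The list median was -0.27 relative to all genes (camera adjusted p = 0.0105 with the preset correlation, and adjusted p = 0.976 with an estimated correlation, where the call was lost). After surface removal the preset correlation gave 0.000655, and that call too was lost (adjusted p = 0.993 with an estimated correlation). The median was -0.21 with the surface removed, -0.20 without replicate 1, -0.20 without replicate 2 and -0.43 without replicate 3.

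Of the cytosolic ribosomal protein genes, too, more fell than rose. Of 34 measured members, 18 fell and 0 rose in both fits. Rpl10 had a log2 ratio of -0.66, Rpl23 of -0.66, Rpl14 of -0.62 and Rpl8 of -0.53. Dimmer kept probes lay at 0.04 and -0.43 for Rpl23 and at 0.01 and -0.43 for Rpl14. Those of Rpl10 lay at -0.49 and -0.38 and that of Rpl8 at -0.29. After surface removal, the probes used lay at -0.53 for Rpl10, -0.49 for Rpl23, -0.38 for Rpl14 and -0.25 for Rpl8. The dimmer probes then lay at 0.14 and -0.13 for Rpl23 and at -0.09 and -0.11 for Rpl14. Those of Rpl10 lay at -0.16 and -0.07 and that of Rpl8 at -0.006. No dimmer probe lay as low as the probe used for its gene. Before surface removal 23 were lower, 1 higher and 10 did not pass, and 24 and 1 passed when adjusted over the list alone. The list median was -0.29 relative to all genes (camera adjusted p = 4.06e-05, and adjusted p = 0.976 with an estimated correlation). It was -0.22 with the surface removed and -0.16 with the mean of a gene's probes. In Agilent's processed signals it was -0.13, with 8 members lower, 2 higher and 24 not passing, and the list did not pass (camera adjusted p = 0.179). With median centring in place of loess it was -0.91, so its size depends on the normalization. The probes used for the named members were very bright, with a mean log2 intensity from 17.1 for Rpl8 to 17.6 for Rpl10. Whether the falls follow probe intensity was not tested.

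These were the only 2 of 42 lists tested that passed before surface removal. After it 6 passed, the 4 additional ones being collagens, collagen processing, hypoxia and G2/M. All 6 calls were lost with an estimated correlation (camera adjusted p = 0.993 for each). After surface removal that correlation was -0.064 for collagens and -0.029 for hypoxia, below the preset 0.01, and their calls were lost too. With 3 arrays the fit has 2 residual degrees of freedom, so such a loss does not show that correlation among members made a call. Turning the sign of 1 array in camera with the preset correlation gave 7 to 11 called lists before surface removal and 8 to 14 after it. A list call here therefore does not separate a shift shared by the arrays from a difference between them. The lists described were chosen after their values were seen, and none of the others passed before or after surface removal. Among all 16819 genes both fits called 1675 up and 1794 down. The counts of list members that rose or fell were not tested against that share.

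Collagen genes changed in both directions. Of 15 measured collagens, 7 rose and 2 fell in both fits. Col3a1 rose by 1.83 ± 0.37 (SD, n = 3), Col6a1 by 0.82 and Col16a1 by 0.80, while Col1a1, a chain of type I collagen, had a ratio of -1.82 ± 0.21 (SD, n = 3). Col16a1 lay at 0.42 with the surface removed, and a dimmer kept probe of it lay at 0.26 before removal and another near 0. Before surface removal 8 were higher, 2 lower and 5 did not pass, and 8 and 2 passed when adjusted over the list alone. The list median was 0.28 relative to all genes (camera adjusted p = 0.149, then 0.0189 after surface removal, and adjusted p = 0.993 with an estimated correlation). It was 0.18 with the surface removed and 0.17 without replicate 3.

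Among genes of collagen processing and cross-linking, more rose than fell. Of 15 measured, 5 rose and 0 fell in both fits, with P4ha1, a prolyl hydroxylase subunit gene, at 0.50 and the collagen chaperone gene Serpinh1 at 0.40. Without replicate 1, Serpinh1 lay at 0.23 and did not pass (limma adjusted p = 0.0863). Pcolce at 0.51 and Loxl4 at 0.39 did not pass after surface removal. Before it 9 were higher, 1 lower and 5 did not pass, and 9 and 1 passed when adjusted over the list alone (camera adjusted p = 0.149, then 0.00572 after surface removal, and adjusted p = 0.993 with an estimated correlation). The list median was 0.24 relative to all genes and 0.14 with the surface removed.

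Other matrix, protease and adhesion genes moved both ways. Of 28 matrix glycoproteins and proteoglycans, 6 rose and 3 fell in both fits (7 and 5 adjusted over the list alone before surface removal), with the fibronectin gene Fn1 at 0.73, Sparc at -0.71 and Agrn at -0.66, and with Thbs2, well above background in RM1-MXRA7 on 1 array only, lower. Dimmer kept probes lay at -0.20 for Sparc and at -0.27 for Agrn. The median of that list was 0.04 and its mean -0.01. Of 30 matrix proteases and inhibitors, 7 rose and 3 fell (11 and 9 adjusted over the list alone). Mmp3, the stromelysin gene, rose by 1.32, the plasminogen activator gene Plat by 0.85 and the collagenase gene Mmp13 by 0.82, and the gelatinase gene Mmp2 was at least 3.32-fold lower. Of 23 integrin and focal adhesion genes, 4 rose and 3 fell (10 and 3 adjusted over the list alone), with Itga7 at -1.23, Itga6 at 0.52 and Itgb3 at -0.34. With the surface removed, Sparc lay at -0.44, Agrn at -0.39, Plat at 0.51, Itga6 at 0.31 and Itgb3 at -0.17. Camera adjusted p was 0.938, 0.753 and 0.471 for the 3 lists before surface removal.

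Hypoxia genes did not pass as a list before surface removal (camera adjusted p = 0.0769). Their call after it (0.0210) was lost with an estimated correlation (adjusted p = 0.993 with an estimated correlation). Of 21 measured, 9 rose and 0 fell in both fits, with the mitophagy gene Bnip3 at 0.74, Bhlhe40 at 0.64, Hif1a, the hypoxia-inducible factor gene, at 0.57 and P4ha1 at 0.50. Dimmer kept probes lay at -0.12 and 0.13 for Bnip3 and at -0.03 for Hif1a. Before surface removal 13 were higher, 2 lower and 6 did not pass, and 13 and 2 passed when adjusted over the list alone. The list median was 0.27 relative to all genes, 0.11 with the surface removed and 0.064 in Agilent's processed signals.

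More cell cycle genes of G2/M fell than rose. Of 32 measured, 9 fell and 1 rose in both fits, with Cdc20 at -0.47, Hmmr at -0.49 and Ccna2 at -0.44, while the proliferation marker gene Mki67 rose by 0.46 and by 0.17 on a dimmer kept probe. Before surface removal 15 were lower, 3 higher and 14 did not pass, and 15 and 4 passed when adjusted over the list alone (camera adjusted p = 0.149, then 0.00572 after surface removal, and adjusted p = 0.993 with an estimated correlation). Of 31 genes of G1/S and DNA replication, 3 rose and 1 fell (13 and 3 adjusted over the list alone), with Cdc6 at 0.55 and a dimmer kept probe of it at -0.15. After surface removal, Hmmr lay at -0.25, Ccna2 at -0.18, Mki67 at 0.30 and Cdc6 at 0.24. Among 13 cyclins and kinase inhibitors, 2 rose and 2 fell (4 and 2 adjusted over the list alone), with Cdkn1c at -2.80, Ccnd2 at -0.88, Cdkn2c at 0.78 and Rbl2 at 0.64, and a list median of 0.02 beside a mean of -0.15. Of 25 p53 targets, 1 rose and 5 fell (5 and 10 adjusted over the list alone), and Pmaip1, a pro-apoptotic BH3-only gene, was at least 2.71-fold lower. Camera adjusted p was 0.170, 0.967 and 0.249 for these last 3 lists. Without replicate 1 the p53 targets passed as a list, downward (camera adjusted p = 0.0180 with the preset correlation). An estimated correlation was not tried there, and with all 3 arrays it gave a camera adjusted p of 0.976.

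**Figure D4:**
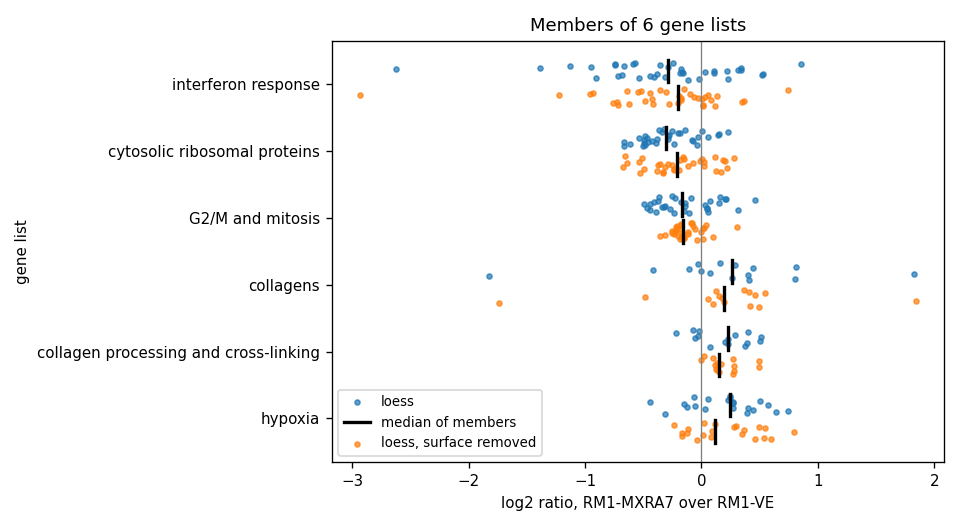
Log2 ratio of RM1-MXRA7 over RM1-VE (horizontal axis) of the members of 6 gene lists (vertical axis), with 1 point per gene and the list median as a bar, after loess and after loess with the surface removed. Relative to all genes the medians after loess lie at -0.27 for interferon response, -0.29 for ribosomal proteins, -0.15 for G2/M, 0.28 for collagens, 0.24 for collagen processing and 0.27 for hypoxia. With the surface removed they lie, in the same order, at -0.21, -0.22, -0.17, 0.18, 0.14 and 0.11.

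Epithelial, mesenchymal and prostate genes gave few large changes. Of 12 epithelial junction and keratin genes, 0 rose and 2 fell in both fits (2 and 4 adjusted over the list alone), with the desmosomal gene Dsp at least 2.45-fold lower and Krt19 at -0.73. Of 19 mesenchymal genes, 3 rose and 2 fell (6 and 2 adjusted over the list alone), with Gsn at 0.51 and a dimmer kept probe of it at 0.0052, Axl at 0.54 and S100a4 at -0.52. Of 8 prostate luminal and androgen response genes, 2 rose and 2 fell (2 and 4 adjusted over the list alone), with Igfbp3 at 0.43 and Sord at -0.40. Of 8 prostate basal and stem genes, 2 rose and 1 fell (4 and 1 adjusted over the list alone), with Sox9 at 0.76, Itga6 at 0.52 and Trp63 at -0.52. Of 11 neuroendocrine genes, 1 rose and 1 fell (3 and 1 adjusted over the list alone), with Uchl1, well above background only in RM1-MXRA7, higher and Syp at -0.29. With the surface removed, Gsn lay at 0.27, Axl at 0.32, Sord at -0.19, Itga6 at 0.31 and Trp63 at -0.32. Camera adjusted p was 0.414, 0.570, 0.783, 0.639 and 0.507 for these lists before surface removal.

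Among angiogenesis and TGF-beta genes, more rose than fell. Of 26 angiogenesis factors, 11 rose and 3 fell in both fits (14 and 7 adjusted over the list alone), with Serpinf1, which encodes an inhibitor of angiogenesis, at -1.63, Pdgfb at -0.93 and Nrp2 at 0.83. Sema3a, well above background in RM1-VE on 2 of 3 arrays, was higher. Dimmer kept probes lay at -0.68 for Serpinf1 and at 0.41 for Nrp2. Of 24 TGF-beta genes and SMAD targets, 8 rose and 1 fell (10 and 4 adjusted over the list alone), with the receptor gene Tgfbr1 at 0.78 and Ltbp3 at 0.75 and with Pmepa1, well above background in RM1-VE on 2 of 3 arrays, higher, while dimmer kept probes lay at -0.07 for Tgfbr1 and at 0.079 for Ltbp3. Of 9 imprinted and embryonic genes, 1 rose and 3 fell (1 and 5 adjusted over the list alone), with Igf2bp3 at 1.07, Cdkn1c at -2.80, Grb10 at -0.84 and Igf2r at -0.37. After surface removal, Nrp2 lay at 0.54, Tgfbr1 at 0.50 and Ltbp3 at 0.37. Camera adjusted p was 0.218, 0.162 and 0.165 for the 3 lists before surface removal. Without replicate 1 the imprinted and embryonic genes passed as a list, downward (camera adjusted p = 0.00184 with the preset correlation). An estimated correlation was not tried there, and with all 3 arrays it gave a camera adjusted p of 0.976.

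Markers of other cell types and genes of antigen presentation gave few changes. Of 6 measured endothelial markers, 0 rose and 1 fell in both fits (0 and 5 adjusted over the list alone), Cdh5 at -0.87. Of 8 macrophage and myeloid markers, 1 rose and 1 fell (2 and 2 adjusted over the list alone), Cd14 at 0.34 and Fcer1g at -0.36. Of 6 lymphocyte markers, 0 changed in both fits (0 and 2 passed when adjusted over the list alone), with Cd3e at -0.29 and Cd4 at -0.26. Of 16 genes of MHC class I antigen presentation, 0 rose and 3 fell (2 and 6 adjusted over the list alone), the immunoproteasome genes Psmb9 and Psmb8 at -1.06 and -0.86 and H2-M3 at -0.54. With the surface removed, Cd14 lay at 0.18, Fcer1g at -0.20 and H2-M3 at -0.32. Camera adjusted p was 0.243, 0.960, 0.502 and 0.482 for the 4 lists before surface removal.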

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

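The surface removal was chosen after the data were seen, and the other alternatives before. Mxra7 had a log2 ratio of -0.034 in Agilent's processed signals and in the series matrix values and of -0.012 with the surface removed, past the threshold in none of them (limma adjusted p = 0.696, 0.697 and 0.893), and kept 0.31 without its call in single channels with no replicate block (adjusted p = 0.142). The number of genes changed went from 7963 to 4116 in Agilent's processed signals, 4087 in the series matrix values, 14259 with no normalization, 2323 in single channels with no replicate block and 5243 with the surface removed, against 7377 with the array as a replicate block. Genes differing at least 2-fold went from 189 to 325 with normexp offset 0, 459 in Agilent's processed signals and in the series matrix values, 662 with median centring and 1595 with no normalization. Lists called went from 2 to 5 in Agilent's processed signals, the series matrix values and with no filter, 6 with median centring, no normalization or the surface removed, and 1 in single channels with no replicate block. Camera with an estimated correlation called 0 lists, 0 also at an unadjusted p under 0.05, whereas fry, which does not compare a list with other genes, called 1 by direction (imprinted and embryonic genes) and 41 in either direction. Median centring and no normalization moved the median of all genes by -0.29 and -0.53 and split the calls into 954 up and 9868 down and into 215 up and 14044 down, so gene and list values there are relative to that shift. Pcolce was reversed in both, at -0.026. Leaving out each array in turn gave 5069 to 7576 genes changed, 191 to 198 at least 2-fold, 2 to 4 lists and 0.27 to 0.39 for Mxra7, whose call was lost without replicate 2 (adjusted p = 0.0693). The number of genes changed was 5069 without replicate 2, and 4 lists were called without replicate 1, which added p53 targets and imprinted and embryonic genes (camera adjusted p = 0.0180 and 0.00184). Without replicate 2, G2/M was added (0.0287), and median centring added G2/M (0.00271), MHC class I antigen presentation (0.0144), glycolysis (0.00431) and oxidative phosphorylation (0.00205). The cause was not tested, except that an offset by construction draws the ratios of dim spots toward 0. Interferon response passed in every alternative fit with camera's preset correlation but single channels with no replicate block. The medians of the 6 lists called before or after surface removal kept their sign in all fits. With median centring they lay, relative to all genes, at -0.91 for ribosomal proteins, -0.39 for G2/M, -0.27 for interferon response, 0.13 for collagens, 0.078 for collagen processing and 0.12 for hypoxia. Of 149 genes chosen by the naming rule besides Mxra7, 126 kept their direction and side of the threshold with the surface removed, 118 in Agilent's processed signals and 111 in single channels with no replicate block. A slide or scan block was not run, since all arrays share 1 slide and 1 scan date. Signal over background limits 28 of the 189 genes to a bound.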

Other observations

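Lists of immune signalling and stress that were not described above, chosen after their values were seen, held genes that changed in both fits. So did all genes tested, with 3469 of 16819, and the counts below were not tested against that share. Of 13 chemokines, 3 rose and 3 fell (4 and 4 adjusted over the list alone before surface removal), with Ccl8 higher by 2.15-fold, Ccl5 at -0.81 and Ccl17 at -0.52. Of 22 inflammatory genes, 3 rose and 3 fell (7 and 4 adjusted over the list alone), with Lcn2, the lipocalin-2 gene, at -0.74, Vcam1 at 0.62 and Csf1 at 0.64. Dimmer kept probes lay at 0.0030 for Vcam1 and at 0.37 and 0.063 for Csf1. Of 27 apoptosis regulators, 6 rose and 1 fell (9 and 3 adjusted over the list alone), with the caspase gene Casp1 at -1.05 and the BH3-only gene Bmf at 0.93. Of 32 genes of ER stress and the amino acid response, 6 rose and 3 fell (12 and 7 adjusted over the list alone), with Sel1l at 2.01, Nupr1 at 0.57 and Trib3 at -0.45. Of 19 oxidative stress genes, 1 rose and 3 fell (5 and 5 adjusted over the list alone), with Gclc, for glutathione synthesis, at 0.84, Gstp1 at -0.65 and Cat, the catalase gene, at -0.47, with dimmer kept probes at -0.16 for Cat and at -0.37 for Gstp1. Of 13 heat shock genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone), with Hspb1 at -1.05 and Cryab at -0.63, a list median of 0.06 and a mean of -0.07. After surface removal, Vcam1 lay at 0.27, Cat at -0.28 and Cryab at -0.41. None of these 6 lists passed camera before or after surface removal, the smallest adjusted p being 0.161.

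Of 18 fatty acid genes, 3 rose and 3 fell in both fits (6 and 3 adjusted over the list alone before surface removal), with Fabp5 at 1.71, Pparg at 0.39 and Elovl5 at -0.47. Of 20 growth factor receptors and ligands, 5 rose and 1 fell (5 and 2 adjusted over the list alone), with Fgfr1 at 0.67, Nrg1 at 0.44 and Gdf15 at -0.81, while dimmer kept probes of Fgfr1 lay at -0.04 and 0.16 and Nrg1 lay at 0.29 without replicate 1. Of 11 Notch pathway genes, 3 rose and 3 fell (4 and 4 adjusted over the list alone), with the ligand gene Dll1 at 0.76, Hes1 at 0.47 and Notch3 at -0.73. With the surface removed, Elovl5 lay at -0.25, Fgfr1 at 0.39, Nrg1 at 0.28 and Hes1 at 0.27. None of these 3 lists passed camera before or after surface removal. The 1 measured gene of the erythroid list, Hbb-bh1, was well above background in RM1-MXRA7 on 2 of 3 arrays and did not pass after surface removal.

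Of the tests below, those of slide position on spots of 1 probe and of GC content were set before their result was seen, and all others were chosen only after it. About the large number of small calls, slide position may account for part of them, since spots of 1 probe in the first rows of the array exceeded those in the last rows by 0.54, 0.61 and 0.50 on arrays 1, 2 and 3 (median of 201 probes spotted 10 times), and by 0.03, 0.06 and 0.04 with the surface removed. The removed surface as the whole cause is argued against: of the genes called from 2 arrays with the surface left in, 82.3%, 90.1% and 78.1% had the same sign on array 1, 2 or 3, left out of the call, once its surface was removed, where 50% would be so by chance. A position effect finer than that surface stays open. Dye bias of single probes cannot be told apart from a difference between the lines, because all 3 arrays have RM1-MXRA7 in Cy3. The 4 sign patterns of the arrays are too few for a share under 0.05: the real pattern gave 7963 genes changed against at most 0 in the others, 189 at least 2-fold against at most 0, and 2 lists against at most 11, so that 1, 1 and 4 of 4 patterns gave as many. A biological difference between the lines remains open and untested.

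The transfected gene lay near a ratio of 1. Dyes exchanged between the lines stay open, since a ratio of -0.012 with the surface removed shows no strong excess of Mxra7 in either channel. Strongly compressed ratios across the arrays are argued against by the spike-in slopes, the lowest being 0.848. The slopes do not settle this for the dimmer Mxra7 probe, since the offset of 50 draws the ratios of dim spots toward 0. That probe lay at 0.10 before surface removal and at 0.18 in Agilent's processed signals. Probes outside the transfected sequence could hide a raised transcript, and this stays open: 2 sense reading frames were open across the brighter probe, which does not place it in or out, and the sequence itself was not analysed here. A transfected line without raised Mxra7 RNA also stays open and untested.

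Chromosome 11, which carries Mxra7, had slightly lower ratios along its length. Slide position and GC content are argued against by a median of -0.070 relative to other genes with the surface removed and of -0.069 with the GC trend removed as well. Fewer copies of the whole chromosome in part of the RM1-MXRA7 cells stay open. Of its 13 bins of 10 Mb, 100% lay below other genes, but that restates the lower ratios along its length and cannot decide. DNA was not measured, and 2 other chromosomes, among them chromosome 12, had over 80% of bins below. For the 18 genes of distal chromosome 12 that rose at least 2-fold, a gain of the whole segment is argued against by the median of -0.035 (bootstrap SD 0.0155) of its 375 genes. A gain that raises the whole stretch with 8 of the 18 at least 2-fold is argued against. Of the 21 genes tested there, 38.1% lay 2-fold or more up with the surface removed (exact 95% interval 18.1% to 61.6%). The risers set the ends of the stretch and its genes are not independent, so that interval is only a rough guide. A gain under 2-fold could not pass this test and stays open, with a median of 0.098 for the other 13 genes. The argument holds as far as the probes of the other 13 genes see only RNA of the stretch, which was not tested. Smaller pieces within it stay open. No biological explanation was tested for either chromosome.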
